A study of Homo sapiens with 6 samples.

How the data were processed

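HES2 human embryonic stem cells were grown on mouse embryonic fibroblasts in medium with a serum replacement, per the labels. They were treated with cycloheximide (10 µg/ml, 10 min), which holds ribosomes on mRNA, then lysed and freed of nuclei, and the lysate was run on a sucrose gradient at 55000 rpm for 16 h. Per the labels, gradient fractions of 60 µL were taken from the top, fractions 1 to 16 were pooled as cytosol and 28 to 37 as membrane, and 500 ng of RNA per sample was amplified and labelled for Illumina Human-6 version 2 arrays. The series' design text gives 3 consecutive passages of the line, so the 3 replicates of each fraction are separate cultures of 1 cell line. The p-values of single genes describe the spread between passages of that line. List tests with a preset correlation and permutations of genes rest on the spread across genes instead.

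The values used are the linear intensities of the deposited series table, 48687 probes on 6 arrays, mapped to samples by sample identifier. BeadStudio and RMA are named in the submitters' processing notes with no role or order. As deposited, the intensities are all above 0 and differ between arrays in median and upper quartile, so they were not made equal between arrays. Whether and how their background was adjusted is not given in the sources used here. Median deposited intensities were 12.6, 12.6 and 14.5 for cytosol 1 to 3 and 10.5, 10.6 and 13.2 for membrane 1 to 3. A scanner table from BeadStudio 2.3.41 with background normalization, per the file headers, was not used: its columns are named by chip position, which no sample label holds, so 48 columns of per-sample values for 6 arrays were left out. Detection p-values and chip membership were therefore not used, and no array batch is named in the labels.

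Intensities were quantile-normalised between arrays, 16 was added, and log2 was taken (limma 3.58.1, R 4.3.3). Probes were kept if the normalised intensity was at least 50 on at least 3 of 6 arrays, which left 13259. The planned background correction with control information and the planned filter on detection p needed the scanner table, and the offset and intensity floor stand in their place; the floor was chosen after the distribution of intensities was seen and before any test. Probe annotation gave 1 gene symbol for 23675 probes, several for 35 and none for 25012; 0 symbols needed updating through the gene table. Each gene was represented by the probe with the highest mean log2 value over all 6 arrays, and unnamed probes stayed as rows of their own (2190 of 12388). Of 751 genes with more than 1 kept probe, 80 had probes of opposite sign and 33 had probes that passed in opposite directions. Where all 3 arrays of a fraction lay below the floor, "at least N-fold" is the brighter fraction's mean log2 value minus log2 of the floor plus offset.

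Membrane and cytosol were compared with limma (lmFit, eBayes, 2-sided) with fraction as the only term and Benjamini-Hochberg adjustment over the 12388 genes and unnamed probes. "Passed" means an adjusted p under 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 40 lists with at least 5 measured members. Camera compares the mean statistic of a list with that of all other genes, those higher in membrane included. Its p-values therefore do not test the medians relative to all genes printed beside them. A list without genes higher in membrane can pass toward cytosol with a median near that of all genes. Fry, which asks whether the genes of a list move on balance one way, passed for 39 of the 40. It tests against 0, whose place depended on the scaling, and was run in the main analysis only. A list at the median of all genes can therefore pass: junction plaque proteins, at -0.05 relative to all genes, did (fry adjusted p = 0.00171). The 42 lists hold 1194 genes, of which 1096 were named on the array and 1004 were measured. The mitochondrially encoded list (0 measured) and the nuclear noncoding RNAs (4 measured) were not tested. List pairs were compared by the difference of medians with 100000 permutations of genes between lists. The groups, the lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated.

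The genes named are the 10 with the largest log2 difference in each direction among those that passed, were at or above the floor on all 3 arrays of the higher fraction and had replicates that did not overlap; in each list the 2 passing members with the largest absolute difference and up to 2 passing members with the largest difference against the list's majority; and 18 genes in every case (POU5F1, NANOG, SOX2, LIN28A, CDH1, EPCAM, TDGF1, PODXL, CD9, FGFR1, HSPA5, SEC61A1, SEC61B, FGF2, XBP1, RPS6, GAPDH and ACTB).

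Membrane and cytosol samples share replicate numbers. Deviations from the group means correlated at 0.49, 0.46 and 0.48 between samples of the same number (across genes, which are not independent replicates) and between -0.32 and -0.1 for other pairs across fractions, so the numbers were taken to pair the samples by passage. Within fractions, arrays correlated at r between 0.97 and 0.99, and no pair held identical values. The model with passage as a block is an alternative.

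Alternatives were median scaling (on probes at or above the floor on all arrays), cyclic loess, an offset of 50, the deposited values with log2 and no scaling between arrays or offset, no intensity floor, the floor on all 6 arrays, the mean of a gene's probes, every probe by itself, eBayes with trend and robust, the passage block, and leaving out each array in turn. No offset and floors of 25 and 100 were added after the data were seen. List pairs used 10000 permutations in the alternatives. The runs that leave out an array had no passage block, so each breaks a passage pair and differences between passages enter them.

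The test was tried on simulated data made from the 12388 genes, with 200 genes changed in 5 runs. It recovered 6% of genes changed 1.5-fold, 49.6% of those changed 2-fold, 84.8% at 4-fold and 98.8% at 8-fold, with 4.46% of calls false and 0 of wrong sign. The simulation drew independent noise on normalised values, without passage pairs or a shift of most genes. These shares therefore do not carry over to the data, where most genes passed and calls depended on the scaling. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.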

Results

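RNA of HES2, an established human embryonic stem cell line, was separated on sucrose gradients into a fraction of membrane-bound polysomes and a fraction of cytosolic (free) RNA, and each fraction was hybridised to Illumina Human-6 arrays. The gradient fractions pooled as cytosol were 1 to 16 from the top, and those pooled as membrane were 28 to 37. The 6 arrays were 3 membrane and 3 cytosol samples, 1 of each from 3 consecutive passages. Of 48687 probes, 13259 passed the intensity floor, and they gave 12388 genes and unnamed probes, of which 10198 were named genes. The arrays differed in brightness before scaling. The upper quartile of the deposited intensities was 75.7 ± 8.41 in cytosol and 41.5 ± 12.8 in membrane (SD, n = 3 each), and the ratio of 1.83 had a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. That test left the passage pairs out. Within pairs the cytosol array was brighter each time (77.0 against 35.4, 66.8 against 32.9 and 83.4 against 56.2). The number of arrays limits the precision of the values that follow.

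The comparison of the 2 fractions asked which mRNAs of these cells were carried on membrane-bound polysomes. mRNAs for secreted, surface, ER, Golgi and lysosomal proteins were higher in the membrane fraction, and those for cytosolic, nuclear and nuclear-encoded mitochondrial proteins lay together near the median of all genes. With quantile normalisation that median was on the cytosol side, a place that depended on the scaling. Of the 12388, 3481 (28.1%) were higher in membrane and 7379 (59.6%) higher in cytosol, and 1528 did not pass (limma, adjusted p under 0.05). A difference of at least 2-fold was found for 3098 toward membrane and 4329 toward cytosol, and one of at least 4-fold for 1958 and 67. The log2 values of membrane over cytosol had their main mode at -1.06, with 54.7% of genes within 0.5 of it, a minimum at 0.55 and a broad second mode at 1.34. Replicates of the fractions did not overlap for 10853 genes (87.6%), against 10% by chance for any 1 gene. Most genes shared the shift of the main mode, which depends on the scaling, so this share depends in part on where 0 was put.

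**Figure D1:**
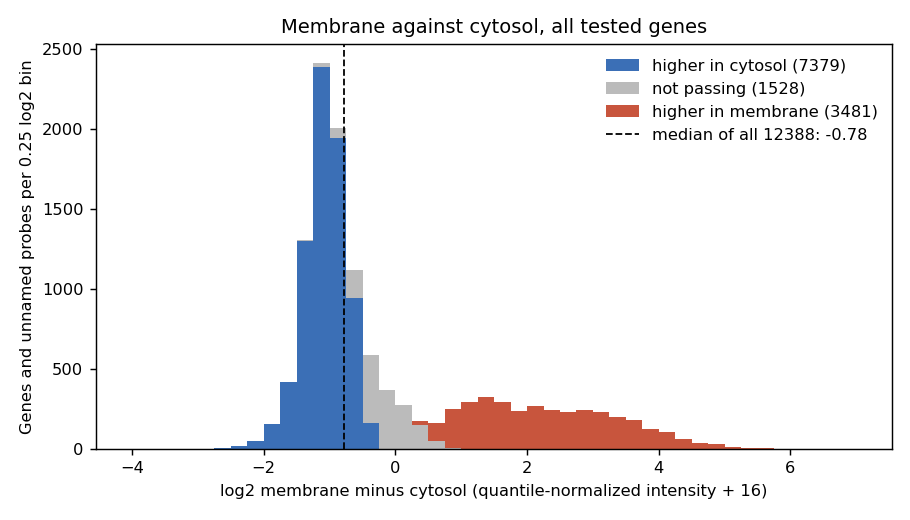
Histogram of the log2 difference of membrane minus cytosol (x axis) for 12388 genes and unnamed probes (y axis, number per bin of 0.25), coloured by the limma call at adjusted p under 0.05. The narrow peak left of 0 holds most of the 7379 genes higher in cytosol, the broad shoulder to the right holds the 3481 higher in membrane, and the dashed line marks the median of all, -0.78, whose place depends on the scaling between arrays.

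The position of 0 depended on the scaling between arrays and other steps of the processing. The median of all genes was -0.78 with quantile normalisation, -0.63 with median scaling, 0.02 with cyclic loess and -1.69 for deposited values without scaling, which here and below also left out the offset of 16. Leaving out the offset alone gave -0.82, and leaving out the intensity floor -0.01, which lowered list values relative to all genes. Of the genes that passed, the share higher in membrane was 32.1% with quantile normalisation, 34.6% with median scaling, 74% with cyclic loess (4242 toward membrane, 1487 toward cytosol) and 22.7% without scaling (2554 and 8713). Of the 3481 genes higher in membrane, 3471, 3477 and 2554 were also called so under median scaling, cyclic loess and no scaling. For the 7379 higher in cytosol these counts were 6825, 1486 and 7379, and 42 were called higher in membrane under cyclic loess. List values below are therefore given as the median log2 and relative to the median of all genes. The relative values depended on the scaling too. Without scaling, medians of the respiratory chain (-1.57), cytoskeleton (-1.57) and translation factors (-1.61) lay above that of all genes. Under median scaling (-0.57, -0.57 and -0.61) they also lay above it, whereas with quantile normalisation they lay below it. Log2 values are of intensity plus 16, which understates the fold of dim genes. Where a fraction lay below the intensity floor of 50 on all 3 arrays, the fold is given as a lower bound.

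The 10 named genes with the largest differences toward membrane were APOA4, TNC, COL6A3, LRP1, VTN, FBLN2, ENPP2, GDF3, LUM and FGA. APOA4, an apolipoprotein, was 62.7-fold higher (log2 5.97, SE 0.52, adjusted p = 2.97e-05, n = 3 per fraction). TNC, the matrix glycoprotein tenascin C, was at least 33.2-fold higher in membrane (adjusted p = 2.91e-06). FBLN2, a fibulin of the matrix, was 38.2-fold higher (log2 5.26, SE 0.21, adjusted p = 1.45e-06), and GDF3, a ligand of the TGF-beta family made by pluripotent cells, 36.5-fold higher (log2 5.19, SE 0.37, adjusted p = 1.00e-05). The log2 values of COL6A3, a collagen VI chain, LRP1, an endocytic receptor, VTN, vitronectin, ENPP2, a secreted lysophospholipase, LUM, the proteoglycan lumican, and FGA, a fibrinogen chain, lay between 5.16 and 5.47. Other kept probes of FGA lay at 5.125 and 3.114. VTN fell to 4.73 and FGA to 4.51 without cytosol replicate 2, and LUM moved to 4.40 without membrane replicate 3 and 5.97 without cytosol replicate 3. Leaving out 1 array breaks a passage pair, so these moves include differences between passages. With passage as a block the limma adjusted p of VTN, FGA and LUM was 2.285e-06 each. In cytosol, COL6A3, LRP1, ENPP2 and LUM reached the intensity floor on 1 of 3 arrays, and APOA4, VTN and FGA on 2 of 3.

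Toward cytosol the largest differences were smaller. CBX1, a heterochromatin protein, was 7.28-fold higher in cytosol (log2 -2.86, SE 0.27, adjusted p = 4.59e-05), and CKS2, a subunit of cyclin-dependent kinases, 6.2-fold higher (log2 -2.63, SE 0.28, adjusted p = 9.64e-05). SOX12, MIR124-2HG, LRRC58, MAST1, DNAJC30, MIB1, SNAP29 and NUDT10 followed with log2 values from -2.52 to -2.29. These 8 genes were dim in membrane: MIR124-2HG, MAST1, DNAJC30 and NUDT10 were below the floor on all 3 membrane arrays, which gives at least 3.67-fold, 2.66-fold, 2.86-fold and 2.9-fold, and SOX12, LRRC58, MIB1 and SNAP29 reached it on 1.

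All 17 measured human embryonic stem cell surface markers were higher in membrane, with a median log2 of 3.18 (3.96 above all genes, or 2.98 with the 3 dim members at their bound; camera adjusted p = 2.9e-10, and adjusted p = 0.0719 with an estimated correlation). CDH3, or P-cadherin, was 26.6-fold higher in membrane (log2 4.73, SE 0.18, adjusted p = 1.45e-06) and CLDN6, a claudin of tight junctions, 18.6-fold higher (log2 4.21, SE 0.26). EPCAM, the epithelial adhesion molecule, PODXL, the podocalyxin that carries stem cell surface epitopes, and CD9, a tetraspanin, had log2 values of 3.26, 3.18 and 3.27 with SE from 0.16 to 0.18. CDH1, or E-cadherin, was at least 8.61-fold higher in membrane (adjusted p = 2.91e-06).

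All 28 receptor kinases were higher in membrane (median log2 3.14, 3.92 above all genes, 3.01 with 1 dim member at its bound; camera adjusted p = 5.56e-13, and adjusted p = 0.0822 with an estimated correlation). PTK7, a pseudokinase of Wnt signalling, and PDGFRB, a receptor of platelet-derived growth factor, led them at log2 4.39 and 3.98. FGFR1, a fibroblast growth factor receptor, was 4.33-fold higher (log2 2.12, SE 0.24, adjusted p = 0.000128). The 18 Wnt and Notch receptors were likewise all higher (median log2 2.96, 3.74 above all genes, 2.84 with 1 dim member at its bound; camera adjusted p = 1.58e-10, and adjusted p = 0.0719 with an estimated correlation), led by NOTCH3 at 4.62 and FZD8, a Frizzled receptor, at 3.67. Of 17 integrins and cadherins, 16 were higher in membrane and 1 in cytosol (median log2 3.59, 4.37 above all genes, 3.14 with 5 dim members at their bound; camera adjusted p = 2.63e-08, and adjusted p = 0.0804 with an estimated correlation). ITGA5, a fibronectin receptor subunit, was 16.5-fold higher in membrane. The exception was ITGAE, an integrin alpha chain, at log2 -0.69 (SE 0.21, adjusted p = 0.0135), which turned to 0.14 under cyclic loess. All 20 claudins and tetraspanins were higher in membrane (median log2 3.21, 3.99 above all genes, 3.21 also with 2 dim members at their bound; camera adjusted p = 1.22e-12), with TSPAN7 at 4.34. The 28 plasma membrane transporters were all higher too (median log2 2.97, 3.75 above all genes, 2.97 also with 1 dim member at its bound; camera adjusted p = 6.58e-14, and adjusted p = 0.0804 with an estimated correlation). Among them SLC2A1, the glucose transporter, stood at 4.34 and SLC39A14, a zinc transporter, at 4.01.

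All 22 genes of basement membrane and matrix were higher in membrane, with a median log2 of 4.19 (4.97 above all genes, 4.03 with 4 dim members at their bound; camera adjusted p = 8.26e-13, and adjusted p = 0.163 with an estimated correlation). FN1, fibronectin, was at least 18.3-fold higher in membrane with its brightest probe, while another kept probe lay lower, at log2 3.08. COL4A2, a collagen IV chain, was 30.4-fold higher (log2 4.93, SE 0.23, adjusted p = 1.80e-06). Of 25 secreted ligands and antagonists, 24 were higher and 1, IGF2 at log2 0.93 (adjusted p = 0.168), did not pass (median 2.84, 3.61 above all genes, and the same with 1 dim member at its bound; camera adjusted p = 6.99e-11). NTS, the precursor of neurotensin, was 16.7-fold higher in membrane, second in this list to GDF3. IGF2 passed toward membrane with passage as a block (adjusted p = 0.000757) and under cyclic loess (1.81, adjusted p = 0.0379).

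Genes of the secretory machinery itself were also higher in membrane. All 27 ER chaperones and oxidoreductases were higher in membrane (median log2 3.35, 4.13 above all genes, and the same with 3 dim members at their bound; camera adjusted p = 3.61e-15). HSPA5, the ER chaperone BiP, was 28.7-fold higher (log2 4.84, SE 0.24, adjusted p = 1.97e-06), and HYOU1, another ER chaperone, 27.4-fold higher (log2 4.78, SE 0.22). All 24 genes of the translocon, signal peptidase and oligosaccharyltransferase (OST) list were higher in membrane (median log2 2.74, 3.52 above all genes; camera adjusted p = 8.78e-14). STT3A and RPN2, subunits of the oligosaccharyltransferase, stood at 4.19 and 4.01, and SEC61A1, the channel subunit of the translocon, at 3.62 (SE 0.14, adjusted p = 1.45e-06). SEC61B, the tail-anchored subunit of the same channel, was not a member of this list, so the count of 24 leaves it out. It was 1.81-fold higher in cytosol (log2 -0.86, SE 0.17, adjusted p = 0.00161), a call lost under cyclic loess (log2 -0.02, adjusted p = 0.936).

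Of 36 glycosylation enzymes and Golgi proteins, 33 were higher in membrane and 1 in cytosol (median log2 2.53, 3.3 above all genes, 2.46 with 3 dim members at their bound; camera adjusted p = 8.78e-14). EXT2 and HS6ST2, both enzymes of heparan sulfate synthesis, stood at 4.56 and 4.32, and the exception was B4GALT2, a galactosyltransferase, at -1.57 (SE 0.29, adjusted p = 0.00126). In GPI anchor synthesis 21 of 23 genes were higher in membrane (median log2 2.39, 3.17 above all genes; camera adjusted p = 3.75e-09, and adjusted p = 0.0804 with an estimated correlation). PIGU and PIGK, subunits of the GPI transamidase, stood at 4.61 and 4.31, whereas DPM1, the catalytic subunit of dolichol-phosphate mannose synthase, and PIGA, of the first step of the pathway, stood at -1.15 and -1.09. Of 26 lysosomal genes, 25 were higher in membrane and 1 did not pass (median log2 3.75, 4.53 above all genes, 3.66 with 2 dim members at their bound; camera adjusted p = 1.10e-14, and adjusted p = 0.0719 with an estimated correlation). CTSD, the protease cathepsin D, and TPP1, a lysosomal peptidase, were 23.1-fold and 22-fold higher.

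Of 30 genes for cholesterol and lipid synthesis in the ER membrane, 26 were higher in membrane, 2 in cytosol and 2 did not pass (median log2 2.7, 3.48 above all genes, and the same with 1 dim member at its bound; camera adjusted p = 4.61e-11, and adjusted p = 0.0719 with an estimated correlation). The sterol enzymes SC5D and DHCR7 stood at 4.8 and 4.3. HSD17B7, a reductase of sterol synthesis, and LPIN1, a phosphatidate phosphatase that is not an integral membrane protein, lay at -0.93 (SE 0.14) and -0.86 (SE 0.30). Another kept probe of HSD17B7 lay at -0.331 and did not pass (limma over every probe, adjusted p = 0.516). Under cyclic loess HSD17B7 turned to 0.06 and LPIN1 did not pass, and LPIN1 also did not pass without cytosol replicate 3 (-0.74, adjusted p = 0.0774) or membrane replicate 2 (-0.56, adjusted p = 0.0555). LPIN1 passed with passage as a block (limma adjusted p = 0.00423). In the unfolded protein response 11 of 16 genes were higher in membrane, 3 in cytosol and 2 did not pass (median log2 2.09, 2.87 above all genes, 2.05 with 1 dim member at its bound; camera adjusted p = 0.0002, and adjusted p = 0.0719 with an estimated correlation). Without scaling this list lay 3.46 above all genes. The membrane-bound sensor ATF6 and the ER membrane protein DERL1 stood at 3.58 and 3.51. XBP1, whose mRNA is spliced at the ER membrane, was 4.18-fold higher in membrane (log2 2.06, SE 0.19, adjusted p = 3.72e-05). The soluble transcription factors ATF3 and ATF4 lay at -1.18 and -0.8. Under cyclic loess ATF3 did not pass and ATF4 turned to 0.12, and under median scaling ATF4 did not pass.

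**Figure D2:**
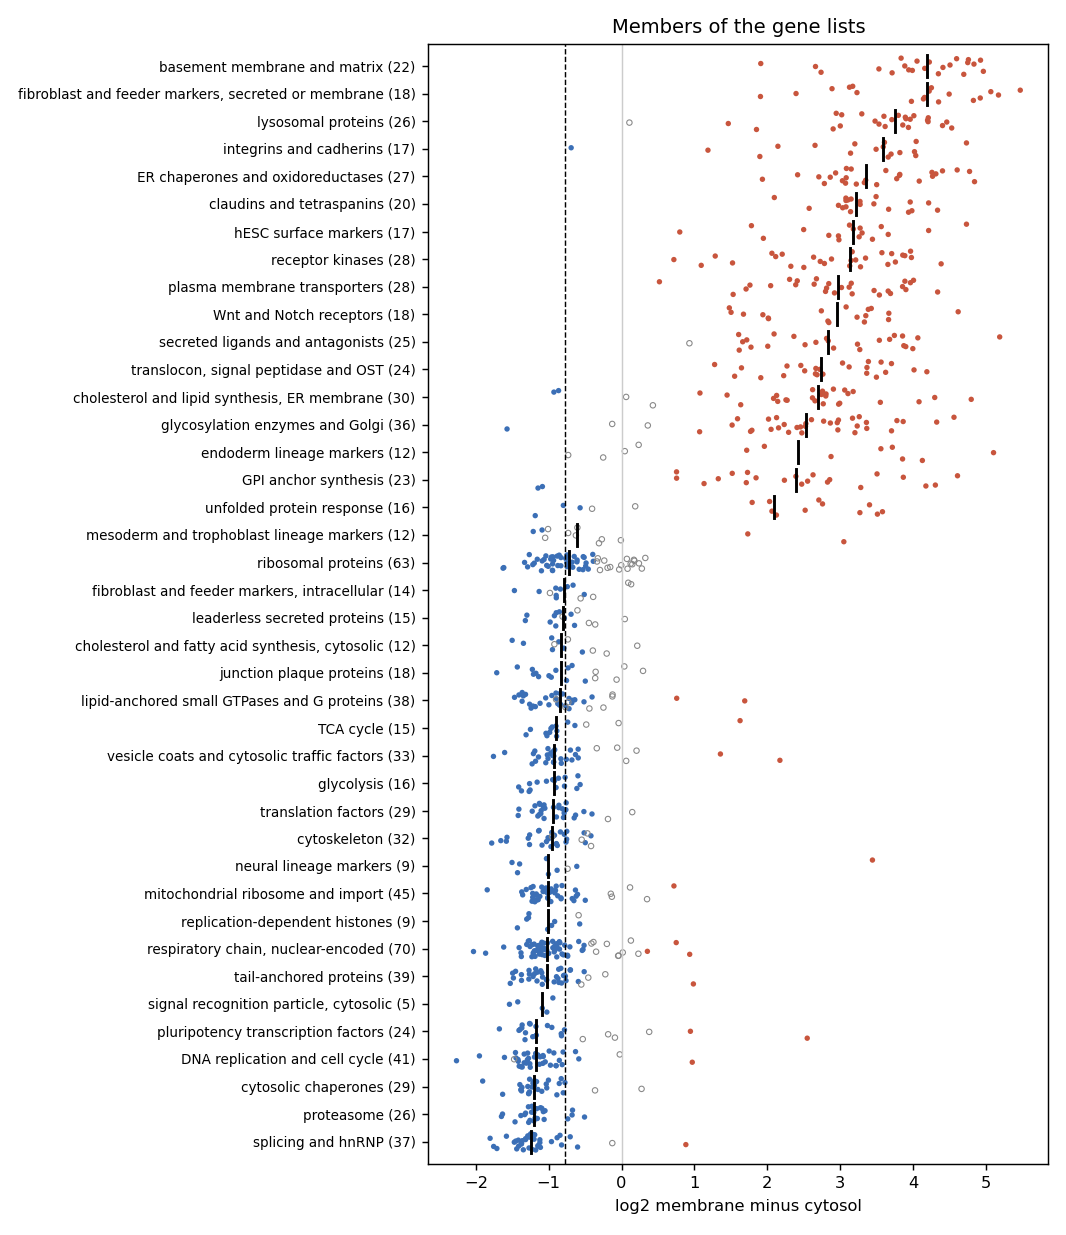
Log2 difference of membrane minus cytosol (x axis) for each measured member of 40 gene lists (y axis, number of members in parentheses), with filled points for genes at adjusted p under 0.05, red toward membrane and blue toward cytosol, and open points for the rest. Black bars are list medians and the dashed line is the median of all genes, -0.78. The 17 lists at the top have medians from 2.09 to 4.19, and the other 23 from -1.25 to -0.62, a range that lies around 0 under cyclic loess.

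Lists of cytosolic and nuclear proteins lay within 0.5 log2 units of the median of all genes. In the splicing and hnRNP list 35 of 37 genes were higher in cytosol, 1 was higher in membrane and 1 did not pass (median log2 -1.25, or -0.47 relative to all genes; camera adjusted p = 0.000117, and adjusted p = 0.165 with an estimated correlation). HNRNPK and SNRPE, both RNA-binding proteins of this machinery, lay at -1.8 and -1.76, and HNRNPL, a splicing regulator, at 0.88 (SE 0.18). SNRPE reached the floor on 1 of 3 membrane arrays. HNRNPL turned to -0.04 when the deposited values were not scaled. Of 41 genes of DNA replication and the cell cycle, 38 were higher in cytosol (median log2 -1.18, or -0.4 relative to all genes; camera adjusted p = 0.000117, and adjusted p = 0.0572 with an estimated correlation). RFC2, a clamp loader subunit, and PLK1, a mitotic kinase, lay at -2.26 and -1.95, and POLA1, a DNA polymerase subunit, lay at 0.97, a call lost without scaling (0.23, adjusted p = 0.405). All 26 proteasome genes were higher in cytosol (median log2 -1.2, or -0.43 relative to all genes; camera adjusted p = 0.000235, and adjusted p = 0.165 with an estimated correlation), with PSMD11 at -1.65 and PSMC4 at -1.63. Of 29 cytosolic chaperones, 27 were higher in cytosol (median log2 -1.2, or -0.42 relative to all genes; camera adjusted p = 0.000583, and adjusted p = 0.122 with an estimated correlation), led by PPIA, or cyclophilin A, at -1.91 and HSPA4 at -1.63.

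All 16 glycolysis genes were higher in cytosol (median log2 -0.93, or -0.16 relative to all genes; camera adjusted p = 0.0159, and adjusted p = 0.458 with an estimated correlation), with TPI1 at -1.41, PGK1 at -1.37 and GAPDH at -1.26 (SE 0.16, adjusted p = 0.000224). In the cytoskeleton list 28 of 32 genes were higher in cytosol and 4 did not pass (median log2 -0.95, or -0.17 relative to all genes; camera adjusted p = 0.00186, and adjusted p = 0.339 with an estimated correlation), with TUBA1A at -1.78, TPM1 at -1.66 and ACTB at -0.97 (SE 0.26, adjusted p = 0.00766). Of 29 translation factors, 27 were higher in cytosol (median log2 -0.93, or -0.16 relative to all genes; camera adjusted p = 0.00183, and adjusted p = 0.149 with an estimated correlation), led by EIF4H and EIF4G2 at -1.42 and -1.41. Of 63 ribosomal protein genes, 46 were higher in cytosol, 45 when adjusted over the list alone, and 17 did not pass. Their median log2 of -0.72 was 0.05 above that of all genes. Camera, which compares means and not medians, placed the list toward cytosol (adjusted p = 0.0147, and adjusted p = 0.499 with an estimated correlation). The genes higher in membrane raise the mean that it compares with. The call was lost under median scaling (camera adjusted p = 0.656) and cyclic loess (0.682), where the sign given by camera was toward membrane. It was also lost without scaling (0.0878), without membrane replicate 1 (0.0701) and without membrane replicate 2 (0.0695). RPS6, a protein of the small ribosomal subunit, did not pass (log2 -0.03, SE 0.14, adjusted p = 0.836) but passed toward membrane under median scaling (0.73) and cyclic loess (0.87). RPL41 and RPS15 lay at -1.63 and -1.62. The RPL41 probe was dim and reached the floor on 1 of 3 membrane arrays, in a list with a median log2 level of 14.38.

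Of 24 pluripotency transcription factors and partners, 18 were higher in cytosol, 2 in membrane and 4 did not pass (median log2 -1.17, or -0.4 relative to all genes, and the same with 1 dim member at its bound; camera adjusted p = 0.0483, and adjusted p = 0.352 with an estimated correlation). The list did not pass without membrane replicate 3 (camera adjusted p = 0.0688). POU5F1, the core pluripotency factor OCT4, was 2.49-fold higher in cytosol (log2 -1.32, SE 0.15, adjusted p = 0.000123), and LIN28A, an RNA-binding protein of pluripotent cells, 2.39-fold higher (log2 -1.25, SE 0.14, adjusted p = 0.000138). SALL1, a zinc finger factor, lay at -1.68. FOXH1, a SMAD partner, was at least 3.45-fold higher in membrane (adjusted p = 1.26e-05). SOX2 lay at 0.94 (SE 0.30, adjusted p = 0.0182) on a probe that reached the floor on 2 of 3 membrane arrays and 1 of 3 cytosol arrays, and did not pass without membrane replicate 2 (0.71, adjusted p = 0.0528) or without the intensity floor (adjusted p = 0.0745). It passed with passage as a block (limma adjusted p = 0.000562). The probes for NANOG, FGF2 and TDGF1 (now CRIPTO) did not meet the intensity filter and were not tested. FGF2 reached the floor on cytosol 2 and 3 only, with 25.6, 61.8 and 65.7 in cytosol and 12.2, 37.1 and 13.4 in membrane. NANOG intensities lay between 7.4 and 9.8 and CRIPTO intensities between 6.9 and 9.6 on the 6 arrays, near the lower end of the scale.

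**Figure D3:**
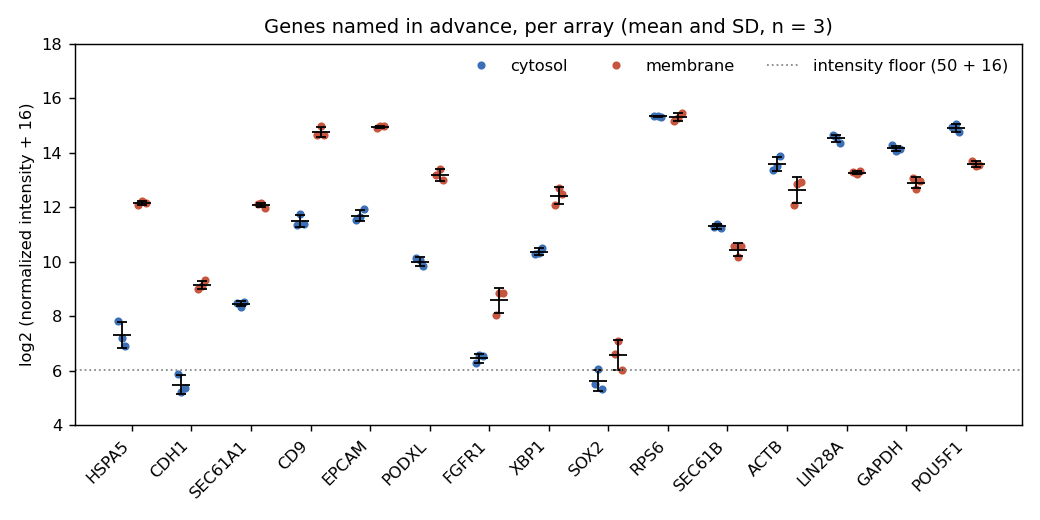
Log2 of normalised intensity plus 16 (y axis) on each of the 3 cytosol (blue) and 3 membrane (red) arrays for 15 genes chosen before the data were examined, with the mean and SD of each fraction in black and the intensity floor dotted. HSPA5 differs most (log2 4.84), RPS6 differs by log2 -0.03 and does not pass, and POU5F1 differs by -1.32 toward cytosol. RPS6 turns toward membrane under median scaling and cyclic loess.

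Nuclear-encoded mitochondrial genes lay on the cytosol side with quantile normalisation. Of 70 genes of the respiratory chain, 58 were higher in cytosol, 3 in membrane and 9 did not pass (median log2 -1.02, or -0.25 relative to all genes; camera adjusted p = 0.000235, and adjusted p = 0.389 with an estimated correlation). ATP5MC3, an ATP synthase subunit that reached the floor on 1 of 3 membrane arrays, and NDUFV1, of complex I, lay at -2.03 and -1.87. The exceptions included the complex I subunits NDUFA13 (0.94) and NDUFA9 (0.75). Of 45 genes of the mitochondrial ribosome and import, 40 were higher in cytosol and 1, the import receptor TOMM20 at 0.72, in membrane (median log2 -1.01, or -0.24 relative to all genes; camera adjusted p = 0.00104, and adjusted p = 0.389 with an estimated correlation). TIMM8B and MRPS14 led the list at -1.84 and -1.37, and MRPS14 reached the floor on 1 of 3 membrane arrays. Of 15 TCA cycle genes, 12 were higher in cytosol, with IDH3B at -1.31, and 1, OGDH at 1.63, was higher in membrane (median log2 -0.9, or -0.12 relative to all genes), and the list did not pass (camera adjusted p = 0.0918). Without scaling between arrays NDUFA13, TOMM20 and OGDH did not pass and NDUFA9 turned to -0.04. No member of the mitochondrially encoded list was named on the array.

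The 4 fixed pairs of lists set proteins of a shared location or pathway but a different route of synthesis against each other, with a 2-sided permutation of genes between lists and Benjamini-Hochberg adjustment over the 4 pairs. Of 15 secreted proteins without a signal sequence, 10 were higher in cytosol, 9 when adjusted over the list alone, and 5 did not pass, with MIF, a cytokine, at -1.32 and TXN, thioredoxin, at -1.3. Their median log2 of -0.81 differed by -3.65 from that of the secreted ligands (permutation p = 5e-05, adjusted p = 5e-05). This list stood at -0.03 relative to all genes and did not pass on its own (camera adjusted p = 0.113). Of 39 tail-anchored proteins, which enter membranes after translation, 35 were higher in cytosol, 1 in membrane and 3 did not pass. Their median of -1.03 (-0.89 with 2 dim members at their bound) differed by -3.77 from that of the translocon list (permutation p = 1e-05, the smallest that 100000 resamples give, adjusted p = 4e-05). Against all genes the list stood at -0.25 (camera adjusted p = 0.00103, and adjusted p = 0.389 with an estimated correlation). The syntaxins STX6 and STX7 lay at -1.53 and -1.49. MCL1, an anti-apoptotic protein, is uncertain, since its brightest probe lay at 0.99 and its second probe at -1.53, both past the threshold, and their mean was -0.27.

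Of 18 junction plaque proteins, which bind the inner side of cell contacts, 13 were higher in cytosol and 5 did not pass, with ZYX, zyxin, at -1.71 and CTNNB1, beta-catenin, at -1.43. Their median log2 of -0.83 (-0.74 with 1 dim member at its bound) differed by -4.42 from that of the integrins and cadherins (permutation p = 2e-05, adjusted p = 4e-05). The list stood at -0.05 relative to all genes and did not pass (camera adjusted p = 0.106). It passed without cytosol replicate 2 (0.0442) and without the intensity floor (0.000105). Of 12 cytosolic enzymes of cholesterol and fatty acid synthesis, 7 were higher in cytosol and 5 did not pass, with PMVK at -1.5 and ACAT2 at -1.35, both enzymes of the early sterol pathway. Their median of -0.83 differed by -3.53 from that of the ER membrane enzymes (permutation p = 4e-05, adjusted p = 5e-05), and the list did not pass against all genes (-0.05, camera adjusted p = 0.182). Its median was 0.05 under cyclic loess, where the all-gene median was 0.02.

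Proteins that act on membranes from the cytosol were mostly on the cytosol side with quantile normalisation. All 5 proteins of the signal recognition particle were higher in cytosol (median log2 -1.09, or -0.31 relative to all genes), with SRP9 at -1.54 and SRP54 at -1.42, and the list did not pass (camera adjusted p = 0.0918). Of 38 lipid-anchored small GTPases and G proteins, 29 were higher in cytosol, 2 in membrane and 7 did not pass (median log2 -0.85, or -0.07 relative to all genes, -0.84 with 1 dim member at its bound; camera adjusted p = 0.00978, and adjusted p = 0.389 with an estimated correlation). RALA lay at -1.47 and RHOG at 0.76, and RHOG turned to -0.11 without scaling. GNAI3, an inhibitory G protein subunit, is uncertain: its probes lay at 1.69 and -0.77, and the gene turned to -0.74 without membrane replicate 1 and to -0.84 without membrane replicate 2, where the other probe was the brighter. Of 33 vesicle coats and cytosolic traffic factors, 27 were higher in cytosol, with SEC23A, a coat subunit, at -1.76. The 2 exceptions were SAR1B and SAR1A, the GTPases that start the same COPII coat, which were 4.51-fold and 2.56-fold higher in membrane (log2 2.17, SE 0.15, and 1.36, SE 0.14). The list median was -0.93 (-0.16 relative to all genes), and the list did not pass (camera adjusted p = 0.0589). It passed with passage as a block (adjusted p = 0.0278), without cytosol replicate 2 (0.021), without the intensity floor (1.54e-05) and at a floor of 25 (0.0439). Of 9 replication-dependent histones, 8 were higher in cytosol (median log2 -1.01, -0.92 with 2 dim members at their bound, -0.24 relative to all genes), with H2BC21 at -1.43 and H2AC18 at least 1.6-fold higher, and the list did not pass (camera adjusted p = 0.0665). H2BC21 reached the floor on 1 of 3 membrane arrays. Of 4 measured noncoding RNAs of the nucleus, too few for a list test, 2 were higher in cytosol, SNHG5 (-0.77) among them, MALAT1 was higher in membrane (0.68) and 1 did not pass. SNHG5 turned to 0.2 under cyclic loess and MALAT1 to -0.07 without scaling.

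The cells were grown on mouse embryonic fibroblasts. All 18 secreted or membrane markers of fibroblasts were higher in membrane (median log2 4.19, 4.97 above all genes, and the same with 2 dim members at their bound; camera adjusted p = 7.65e-11, and adjusted p = 0.0719 with an estimated correlation), led by COL6A3 and LUM. Without the intensity floor the median of this list was 3.60 (3.62 above all genes). Of 14 intracellular fibroblast markers none was higher in membrane and 9 were higher in cytosol (limma), with CNN1, calponin, at -1.47 and TPM2, a tropomyosin, at -1.13, and the list did not pass (median log2 -0.79, or -0.02 relative to all genes; camera adjusted p = 0.244). CNN1 reached the floor on 1 of 3 membrane arrays. Of 12 endoderm markers 8 were higher in membrane and 4 did not pass (median log2 2.42, 3.19 above all genes, and the same with 1 dim member at its bound; camera adjusted p = 0.00288, and adjusted p = 0.352 with an estimated correlation). The endoderm list fell to a median of 1.84 (2.54 above all genes) at a floor of 25 and to 0.98 (0.99 above all genes) without the intensity floor, and passed by camera in both. APOB, the main apolipoprotein of lipoproteins, and AFP, alpha-fetoprotein, were 34.4-fold (log2 5.10, SE 0.66) and 17.5-fold higher. APOB moved to 4.42 without cytosol replicate 2 and to 5.77 without cytosol replicate 1. The 4 that did not pass were the transcription factors FOXA1, FOXA2, SOX17 and EOMES. EOMES passed toward cytosol with passage as a block (-0.73, adjusted p = 0.00125), without scaling (-1.70, 0.0119), without cytosol replicate 2 (-1.06, 0.0472) and without membrane replicate 3 (-1.07, 0.0404). Of 9 neural markers 7 were higher in cytosol, with RAX, a homeobox factor, at -1.5, and 1, the adhesion molecule NCAM1, was at least 6.92-fold higher in membrane. The neural list did not pass (median log2 -1, -0.88 with 2 dim members at their bound, -0.23 relative to all genes; camera adjusted p = 0.443), and RAX did not pass without cytosol replicate 1 (-1.3, adjusted p = 0.0743), cytosol replicate 3 (-1.23, 0.081) or membrane replicate 2 (-0.99, 0.0726). With passage as a block RAX passed toward cytosol (limma adjusted p = 0.00021). Of 12 mesoderm and trophoblast markers, 2 were higher in membrane, 2 in cytosol and 8 did not pass, and adjusted over the list alone 2 were higher in membrane and 0 in cytosol. KDR, a receptor of vascular endothelial growth factor, was at least 4.69-fold and PLAC1 at least 1.53-fold higher in membrane, and the list did not pass (median log2 -0.62, 0.16 above all genes; camera adjusted p = 0.499).

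IGF2, FOXA1, FOXA2, SOX17 and EOMES were named after their values were seen, to identify small counts. Of 40 lists tested, 17 passed toward membrane and 13 toward cytosol by camera with a preset correlation of 0.01. With an estimated correlation 5 kept the call: claudins and tetraspanins, secreted ligands and antagonists, ER chaperones and oxidoreductases, translocon with signal peptidase and OST (adjusted p = 0.04 each), and glycosylation enzymes and Golgi (0.0463). The counts per list were equal when adjusted over the list alone in 37 of 41 lists, and the exceptions were the ribosomal, leaderless, mesoderm and trophoblast, and unfolded protein response lists, the last with 4 in place of 3 toward cytosol. Under cyclic loess, which moved the median of all genes to 0.02, the cytosol calls of GAPDH, ACTB, LIN28A, MIF, TXN, TPI1, PGK1, TUBA1A, PSMC4, CTNNB1, ACAT2, IDH3B, SRP9, DPM1, PIGA, CNN1, TPM2 and RAX did not pass, nor did those of the cytoskeleton, glycolysis, GTPase, pluripotency factor and translation factor lists. Glycolysis and the pluripotency factors also did not pass under median scaling or without scaling, and ACTB and SNHG5 did not pass under median scaling. Without the intensity floor 8 further lists passed toward cytosol, and the calls of CTNNB1, LPIN1, RAX and SOX2 did not pass.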

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

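The alternatives without an offset and with floors of 25 and 100 were chosen after seeing the data. The 4 list pairs kept their direction and passed under every alternative run, with adjusted p from 0.0001 to 0.0009. The count of genes higher in membrane ranged from 2429 to 4242. Leaving out an array in turn gave 2800 to 3405 genes toward membrane and 6394 to 7344 toward cytosol. Of 2322 values of the 127 genes named by rule under alternatives, 2270 kept their call, and their direction where either fit passed. A change of sign with no call in either fit counts as kept, as for RPS6 (0.037 with an array left out). Under cyclic loess 101 of the 127 genes kept their call. Most of these genes were chosen for large differences in the same data, which favours stable calls. With passage as a block, 3570 genes were higher in membrane and 7793 in cytosol, and the vesicle coat list passed (-0.155 relative to all genes, adjusted p = 0.0278); the block changed no other call of these 127 genes, the lists or the list pairs. Of the single genes named after their values were seen, 3 changed call with the block: IGF2 passed toward membrane (0.931, adjusted p = 0.000757), and EOMES (-0.732, 0.00125) and ATP6V0D1 (-0.536, 0.0121) passed toward cytosol. A run without background correction and a chip block were not run, since no background correction was added to the deposited values and chips are not tied to samples. Dim genes set the limit on signal over background: 675 of the tested genes were below the floor on all cytosol arrays and 513 on all membrane arrays.

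Between the scalings of the arrays, the median of all genes was -0.776 in the main analysis, 0.022 with cyclic loess, -0.633 with median scaling and -1.686 without scaling; this last setting also left out the offset of 16, and leaving out the offset alone gave -0.82. Genes at least 2-fold higher in cytosol numbered 4329 in the main analysis, 2870 with median scaling, 245 with cyclic loess, 8369 without scaling and offset and 4727 without the offset alone, and genes higher in cytosol 1487 with cyclic loess. List values here are medians relative to all genes. Their sign could also change: over all alternatives the respiratory chain reached 0.118, the cytoskeleton 0.115 and the translation factors 0.081, from negative values in the main analysis. The ribosomal protein list, at 0.052 in the main analysis, did not pass under median scaling (0.478, adjusted p = 0.656), cyclic loess (0.168, 0.682) or no scaling (0.536, 0.0878). In the first 2 the sign given by camera was toward membrane, while the median log2 itself was -0.155 and 0.19. Under cyclic loess the translation factors (-0.125), glycolysis (-0.107), cytoskeleton (-0.047), pluripotency factors (-0.253) and lipid-anchored GTPases (-0.054) did not pass. Glycolysis and the pluripotency factors did not pass under median scaling (-0.076 and -0.158) or without scaling (-0.024 and -0.109), nor the pluripotency factors without an offset (-0.355). Named genes that turned were RPS6 under median scaling (0.735) and cyclic loess (0.87), ITGAE (0.135), HSD17B7 (0.059), ATF4 (0.118) and SNHG5 (0.201) under cyclic loess, and HNRNPL (-0.035), NDUFA9 (-0.043), RHOG (-0.105) and MALAT1 (-0.067) without scaling. For RPS6, ITGAE, HSD17B7, ATF4 and SNHG5 the change lies in the direction of the shift of the median of all genes. Under median scaling RPS6 moved further than that median did, and the cause was not tested. MCL1 turned to -0.27 as the mean of its probes, which point in opposite directions. GNAI3 ranged from -0.837 to 1.854 when an array was left out, and turned without membrane replicate 1 (-0.744) or 2 (-0.837), where the other probe was chosen.

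With an estimated correlation, which leaves the medians as they are, 25 lists did not pass: surface markers (3.957), receptor kinases (3.916), Wnt and Notch receptors (3.739), integrins and cadherins (4.367), matrix (4.968), GPI anchor synthesis (3.168), plasma membrane transporters (3.746), lysosomal proteins (4.53), ER membrane lipid synthesis (3.475), unfolded protein response (2.87), secreted fibroblast markers (4.965), endoderm markers (3.193), tail-anchored proteins (-0.25), ribosomal proteins (0.052), translation factors (-0.157), proteasome (-0.426), cytosolic chaperones (-0.42), glycolysis (-0.156), cytoskeleton (-0.173), pluripotency factors (-0.395), splicing (-0.471), DNA replication (-0.402), respiratory chain (-0.246), mitochondrial ribosome and import (-0.236) and lipid-anchored GTPases (-0.07). Without the intensity floor, which adds dim probes and moves the median of all to -0.013, 8 more lists passed toward cytosol: junction plaque (-0.815), leaderless secreted (-0.772), signal recognition particle (-1.075), cytosolic lipid synthesis (-0.814), histones (-0.905), TCA cycle (-0.887), vesicle coats (-0.911) and intracellular fibroblast markers (-0.687). The calls of CTNNB1 (adjusted p = 0.0729), LPIN1 (0.0922), RAX (0.117) and SOX2 (0.0745) did not pass there. The endoderm markers fell to 0.989 there and to 2.543 at a floor of 25, and kept their call. Histones also passed with every probe (-0.495) and, with vesicle coats, at a floor of 25 (-0.283 and -0.226). Leaving out an array gave a range of -0.104 to 0.048 for junction plaque, -0.205 to -0.017 for vesicle coats, -0.465 to -0.282 for pluripotency factors and -0.023 to 0.186 for ribosomal proteins. Junction plaque and vesicle coats passed without cytosol replicate 2, and the other lists of these 4 lost their call without membrane replicate 3 (pluripotency) or membrane replicate 1 or 2 (ribosomal). The cause of these changes was not tested.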

Other observations

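The families in this part and the tests on transporters, the vacuolar ATPase, markers of other cell types and discordant probes were chosen after the results were seen; the tests on ribosomal brightness within bins and on other splits were written before, and the 2 further values on ribosomal brightness were added after. Among 170 measured solute carriers outside the SLC25 family, 162 were higher in membrane and 3 in cytosol, with a median log2 of 2.47 (3.25 relative to the median of all genes). Of 27 carriers of the SLC25 family, most of them mitochondrial, 22 were higher in cytosol and 3 in membrane, with a median of -0.7 (0.08 relative to all genes). Under cyclic loess their median was 0.1, again 0.07 from that of all genes, so their place is that of the bulk of genes and not a side of 0. The medians of the 2 groups differed by -3.175 (2-sided permutation p = 1e-05, the smallest that 100000 resamples give, adjusted p = 2e-05 over 2 family comparisons). In the vacuolar ATPase, the 8 peripheral V1 subunits were all higher in cytosol (median -1.11), for example ATP6V1A at -1.2, and none of them passed under cyclic loess (median -0.26). Of 10 V0 and accessory genes, 8 were higher in membrane (median 2.24), with ATP6AP1 at 4.16 and ATP6V0B at 3.23, and the V0 subunit ATP6V0D1, which is not embedded in the membrane, did not pass (-0.54, adjusted p = 0.0943) but passed toward cytosol with passage as a block (adjusted p = 0.0121). These medians differed by -3.355 (2-sided exact permutation p = 0.00759, adjusted p = 0.00759). The families were chosen for these differences, so both comparisons describe them and test no explanation.

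Further families divided in the same way. All 14 semaphorins, all 17 ADAM and ADAMTS proteases and all 9 receptor-type tyrosine phosphatases were higher in membrane, with median log2 values of 2.99, 2.89 and 3.43, as were 28 of 29 collagen chains (3.71) and 23 of 25 protocadherins (2.97). All 22 ubiquitin-conjugating enzymes (UBE2 genes) and 25 of 26 DDX helicases were higher in cytosol, with medians of -1.15 and -1.06, or -0.37 and -0.29 relative to all genes, and 5 and 8 of them passed toward cytosol under cyclic loess. Of 284 numbered ZNF zinc finger genes, 238 were higher in cytosol and 16 in membrane, with a median of -1, or -0.23 relative to all genes; under cyclic loess 64 of 285 passed toward cytosol and 28 toward membrane. The DNAJ co-chaperones split: 19 of 36 were higher in cytosol and 13 in membrane, against 6 and 16 under cyclic loess. The ER members DNAJB11 (3.63), DNAJC1 (3.29), DNAJC3 (3.07), DNAJC10 (2.95) and DNAJB9 (2.71) were among the latter, while the cytosolic DNAJA1, DNAJA2 and DNAJB1 lay at -1.15, -1.26 and -1.2, and did not pass under cyclic loess (-0.22, -0.35 and -0.39).

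For the comparison of membrane and cytosol, the real division of the 6 arrays gave 10860 genes that passed, and the highest of the other 9 divisions into 3 and 3 gave 0, so 1 of 10 gave as many. With 10 divisions the share cannot fall under 0.1. Each other division has arrays of both fractions on both sides, so the difference between fractions adds to its spread and lowers its count. The counts of 0 are therefore no measure of what chance would give. Of the 4 divisions that part all 3 passage pairs, the real one included, the highest other also gave 0.

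With quantile normalisation, ribosomal protein mRNAs lay nearer to parity than other cytosolic genes, by 0.365 in mean log2. Under cyclic loess their median was 0.19, farther from 0 than those of cytoskeleton (-0.025), glycolysis (-0.084) and translation factors (-0.102). Respiratory chain (-0.122) and mitochondrial ribosome and import (-0.148) were also nearer to 0 there. The proteasome (-0.306), splicing (-0.3), DNA replication (-0.284) and cytosolic chaperone (-0.277) lists were farther. Ribosomal protein mRNAs were also brighter, with a median log2 level of 14.4 against 11.7. Within bins of equal brightness (0.5 log2 units wide) the difference was 0.093 (permutation p = 0.26), and the brighter part of the ribosomal list had a median of -0.36 against -0.96 for the dimmer part. The matched value rests in part on the brightest bin, which held 16 ribosomal and 2 other genes; without that bin it was 0.148 (permutation p = 0.0591). Of the 325 other cytosolic genes, 14 lay above the ribosomal median level, with a median log2 of -0.676, which is 0.313 below the 32 brighter ribosomal genes (permutation p = 0.0688). The planned value is the one that compression predicts, but with 14 genes and so few in the brightest bin the 2 explanations cannot be told apart: compression of bright probes and a real share of ribosomal protein mRNA on membranes both stay open.

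Secreted and membrane markers of fibroblasts and endoderm were among the genes highest in membrane. More RNA of another cell type in the membrane fraction would raise that type's intracellular transcripts too, if the gradient had not separated that RNA. Of 14 intracellular markers of fibroblasts, fixed before the data were examined, 0 were higher in membrane (limma, 0 also at an unadjusted p under 0.05), 9 were higher in cytosol and 5 did not pass; with passage as a block 0 were higher in membrane and 11 in cytosol. Their upper quartile was 0.252 log2 units above the median of all genes and their highest 0.908, under the 1 unit that such an excess was set to require. The most abundant, VIM and TPM2, lay at -0.9 and -1.13, or -0.119 and -0.355 relative to all genes. Under cyclic loess neither passed (0.07 and -0.19). VIM also did not pass under median scaling (adjusted p = 0.133), without the intensity floor (0.0613), without cytosol replicate 3 (0.054) or without membrane replicate 2 (0.0515). With passage as a block VIM passed toward cytosol (limma adjusted p = 0.000541). In these lists 5 of the 14 intracellular fibroblast markers and 2 of the 18 secreted ones are also in another list. So none of these 14 markers passed toward membrane. The limit was set after the values were seen, so the comparison describes the markers and cannot decide about an excess of unseparated fibroblast RNA. Whether the stem cells themselves express these markers was not tested. RNA of fibroblasts lysed with the culture would be separated like that of the other cells, which these markers cannot show. The test says nothing about whether such cells, or feeder RNA bound by these probes, were present in both fractions. For endoderm, 4 intracellular markers were measured: FOXA1 (0.24), FOXA2 (0.05), SOX17 (-0.25) and EOMES (-0.73). They lay 0.044 to 1.011 above the median of all genes, with an upper quartile of 0.868, and none of the 4 passed (limma, 0 also at an unadjusted p under 0.05). With passage as a block FOXA1 (adjusted p = 0.134), FOXA2 (0.747) and SOX17 (0.198) did not pass, and EOMES passed toward cytosol (0.00125). With 4 markers that near the limit, an excess of endoderm RNA in the membrane fraction stays open.

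For 33 genes, probes of the same gene passed in opposite directions. ABCC5, a transporter, was 8.7-fold higher in membrane with 1 probe (log2 3.12) and higher in cytosol with the other (-1.23), and the ER channel protein CLCC1 gave 3.94 and -1.24. Probes for different transcript forms are a candidate explanation: probes of 22 of the 33 genes (66.7%) came from different transcript accessions, against 294 of 572 (51.4%) genes with probes that passed in the same direction (odds ratio 1.889, Fisher's exact p = 0.107). A dim probe near background is another: the dimmer probe of these genes had a median log2 level lower by a difference of -0.353 (permutation p = 0.329). Neither test decided between them, and the 2 explanations cannot be told apart with 33 genes. The 2 probes of CLCC1 share an accession, so different transcript accessions do not account for that gene.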
